A study of Mus musculus with 6 samples.

How the data were processed

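Gene expression was measured by RNA sequencing in 6 libraries of mouse bone marrow-derived macrophages kept in osteoclast-inducing culture for 5 days, 3 without and 3 with Visomitin. Per the labels, RNA was taken up in TRIzol, treated with DNase I and made into stranded mRNA libraries for Illumina sequencing. The authors' notes name fastp, HISAT2 and StringTie for read processing; their versions, the genome build, the annotation and the program that counted reads are not given in the sources used here. The deposited values are TPM, a share of all transcripts scaled to a fixed total, which the authors computed per gene within each library, so that each library has the same sum. They were used as deposited, with no further scaling between libraries. TPM keep neither counts nor depth, so no counting interval can be given, and the number of libraries limits the precision.

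The table holds 57180 Ensembl gene identifiers with no gene symbols, and 34857 of them are listed at 0 in all libraries. Symbols came from a reference table of gene names and were found for 51884 identifiers. Of tested identifiers, 8 share a symbol with a more abundant one, and these appear under their identifier. Genes with at least 1 TPM in at least 3 of the 6 libraries were tested, 11753 in all, of which 11554 have a symbol. Values were transformed to log2(TPM + 1) with a pseudocount of 1 and fitted with limma 3.58.1 (lmFit and eBayes with a trend, statmod 1.5.0, R 4.3.3) with group as the only term. Differences are Visomitin minus control, tests are two-sided, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. A size filter of 2-fold was applied for a separate count. Exact permutation tests of the group labels accompany Stat3, Ldhb and Ldha, and 3 against 3 libraries cannot give a p under 0.1. On simulated data with 11753 genes, of which 200 were changed, 55.1% of genes were recovered at 1.5-fold, 89.2% at 2-fold and 98.3% at 4-fold. Of the calls, 4.71% were false. The simulated noise was independent between genes, with no difference shared by a whole library, so these rates may not hold for the real libraries.

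Gene lists, 33 in number, were written before the data were examined. Of these, 26 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The estimate rests on 4 residual degrees of freedom, so that form of camera has little power here. A list that misses it is not shown to be unchanged. The other 7 lists are markers of other cell types and are reported by their members. The tests, the named genes and 16 alternatives were also set before the data were examined. The named genes are Stat3, Ldhb and Ldha, with Nfatc1, Acp5, Ctsk, Dcstamp and Mmp9, whatever their result. Added to these are the 10 genes with the largest rise and the 10 with the largest fall. These had to pass the test, have group ranges that do not overlap, reach a mean of 5 TPM in the higher group and have a symbol that is not a predicted gene or a clone name. From each list came the tested members with the lowest p-values, up to 4 for the main lists and up to 3 for the others. The rule asked for a symbol in the table itself, and since the table has none, the reference symbols were used. Other genes are named as chosen after their values were seen. A few genes that the rule names are not reported here.

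The alternatives were pseudocounts of 0.1 and 5, no filter on low values, a filter of 5 TPM on the mean, and median-ratio scaling or quantile normalization. Mitochondrially encoded genes were left out, the trend was dropped, array weights and a block for the library number were added. Each library was also left out in turn. Such a fit has fewer residual degrees of freedom than the 4 of the main fit, which lowers power. A call lost in it need not depend on the library left out. Protein-coding genes only, and a correction for transcript length and GC content, were added after seeing the data. The labels state no pairing, so the main fit did not pair libraries by the numbers in their names. Residual correlations within a number were 0.05, 0.02 and 0.17, which neither shows nor excludes pairing. Nuclear genes sharing at least 50% of their 31-base words with mitochondrially encoded genes were treated as near-identical copies. At most 0.391% of tested genes had identical TPM in any pair of libraries, so no library repeats another. Protein levels and STAT3 phosphorylation were not analysed here.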

Results

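RNA was sequenced from mouse bone marrow-derived macrophages, primary wild-type cells that can fuse into bone-resorbing osteoclasts. The cells had spent 5 days in osteoclast-inducing culture with Visomitin or without it. Visomitin, also known as SkQ1, is a plastoquinone antioxidant coupled to a cation that draws it into mitochondria; its dose is not given in the sources used here. The 6 libraries form 2 groups of 3, named control 1 to 3 and Visomitin 1 to 3. Whether they came from separate mice or cultures is not given in the sources used here, so every p-value measures only the spread between these libraries, which may be technical. Expression is in TPM, a share of each library's transcripts that keeps no sequencing depth, so the depth of each library is unknown. Between 11551 and 11821 genes reached 1 TPM per library. The first principal component, with 44.1% of the variance, separated the groups. The second, with 19.6%, set Visomitin 1 (25.1) apart from Visomitin 2 (-17.2) and Visomitin 3 (-16.8). Pearson correlations of log2 values across genes were 0.979 to 0.987 within groups and 0.961 to 0.976 between them; genes are not independent replicates.

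Ldhb, which encodes the B subunit of lactate dehydrogenase, fell 3.84-fold with Visomitin on the log2(TPM + 1) scale, as all folds here, and the genes of the mature osteoclast fell with it: Ctsk 4.65-fold, Acp5 4.25-fold and Dcstamp 7.70-fold. Of the genes of the proton pump 11 of 16 fell, of the tricarboxylic acid cycle 13 of 24 and of the nuclear-encoded respiratory chain 18 of 75. For these genes and for Ldhb, bulk RNA cannot tell a smaller share of osteoclasts from lower expression in each cell. Of 22 ATF4 target genes 9 rose, with Trib3 up 6.37-fold and Ddit3 up 2.65-fold. These 4 lists passed limma's camera test at a preset correlation and not with an estimated correlation (adjusted p of 0.33 to 0.39). The comparison asks what Visomitin changes in cells under osteoclast differentiation, and the title of the study names STAT3 and LDHB. Stat3 transcript did not pass the test, at 38.4 ± 1.72 TPM in control and 45.4 ± 4.30 TPM with Visomitin (SD, n = 3; limma adjusted p = 0.19).

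Of 11753 genes tested, 835 passed an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), 244 higher and 591 lower with Visomitin, so that 70.8% were lower. At least a 2-fold change on the log2(TPM + 1) scale was seen for 199 of them, 37 higher and 162 lower. All 835 had group ranges that did not overlap, as did 3568 genes or 30.4% of those tested, where chance gives 10%. Unadjusted p-values under 0.05 numbered 2862. The share of lower genes depended on scaling. After median-ratio scaling 481 were higher and 689 lower, and after quantile normalization 559 and 651. A length and GC correction chosen after seeing the data gave 709 and 756. The median log2 fold change of all tested genes was -0.034 in the main fit and 0.003, 0.023 and 0.026 under these settings in turn. The total was 299 without control 1, 443 without control 2, 362 without control 3 and 359 without Visomitin 2. Fits without a library have fewer residual degrees of freedom, so a lower count need not depend on the library left out. The higher genes numbered 67 without control 1, 118 without control 2, 83 without control 3, 411 without Visomitin 1, 54 without Visomitin 2 and 126 without Visomitin 3. The lower genes numbered 232 without control 1, 325 without control 2, 279 without control 3 and 305 without Visomitin 2. With no filter on low values 33 of the 79 calls among named genes were lost, among them Slc16a7 (0.056), Chac1, Calr and Clec10a (0.052 each), and without the trend 18 were. The deposited table lists genes by identifier: Ldhb is ENSMUSG00000030246, Stat3 ENSMUSG00000004040, Ldha ENSMUSG00000063229, Ctsk ENSMUSG00000028111, Acp5 ENSMUSG00000001348, Dcstamp ENSMUSG00000022303 and Nfatc1 ENSMUSG00000033016. All fold changes are on the log2(TPM + 1) scale, which understates the change of low genes, and all adjusted p-values of genes are limma's.

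**Figure D1:**
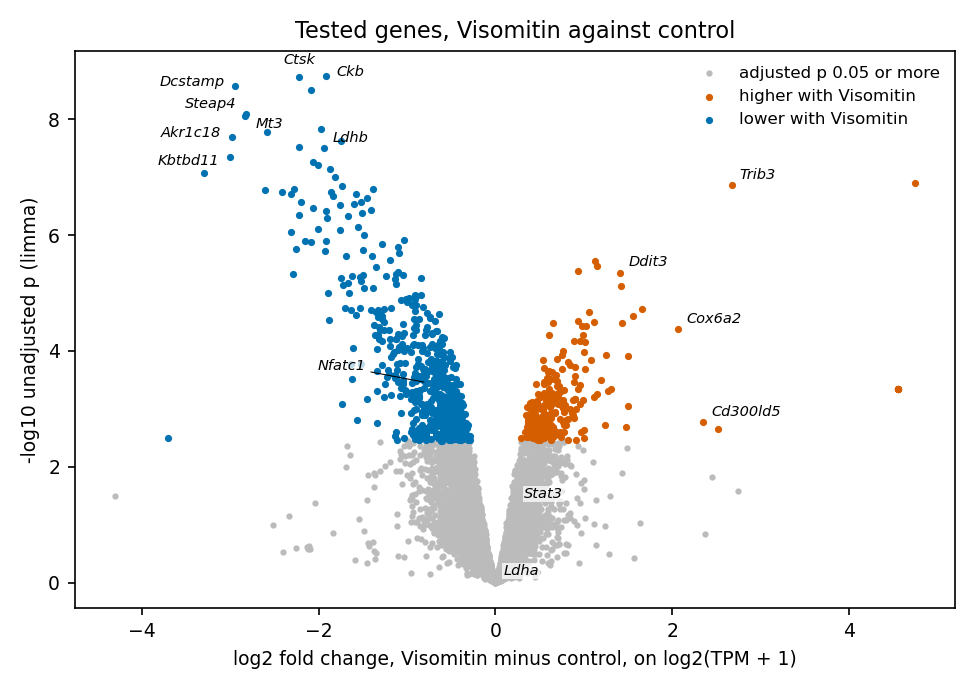
Each point is 1 of the 11753 tested genes, with its log2 fold change (Visomitin minus control, on the log2(TPM + 1) scale) on the x axis and -log10 of its unadjusted limma p on the y axis. The smallest p-values belong to genes among the 591 lower (blue), not among the 244 higher (orange); grey genes did not pass an adjusted p of 0.05, among them Stat3 and Ldha.

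Osteoclast genes fell as a group. Of the 40 tested members of the list for osteoclast differentiation and resorption, 28 fell, 0 rose and 12 did not pass, with a median log2 fold change of -0.79; adjusted over the list alone, 32 fell. Ctsk, the collagen-degrading cathepsin of osteoclasts, went from 3046 ± 220 to 654 ± 30.5 TPM (SD, n = 3; log2 fold change -2.22, SE 0.08, adjusted p = 8.99e-06). Acp5, the tartrate-resistant acid phosphatase, went from 4298 ± 240 to 1011 ± 64.0 TPM (-2.09, SE 0.08, adjusted p = 8.99e-06). Dcstamp, needed for fusion of precursors, went from 178 ± 16.6 to 22.3 ± 2.71 TPM (-2.94, SE 0.11, adjusted p = 8.99e-06). Ckb, the brain-type creatine kinase, went from 2115 ± 87.7 to 560 ± 12.9 TPM (-1.92, SE 0.07, adjusted p = 8.99e-06). Mmp9, a secreted gelatinase, fell from 3838 ± 124 to 1476 ± 250 TPM (-1.39, SE 0.12, adjusted p = 0.00046). Car2, the carbonic anhydrase that supplies protons for resorption, and Siglec15, a sialic acid receptor of osteoclasts, fell 5.99-fold and 5.32-fold. Nfatc1, the transcription factor that directs osteoclast differentiation, fell least among the genes named here, from 87.1 ± 1.91 to 51.6 ± 9.27 TPM (-0.76, SE 0.13, adjusted p = 0.014). It missed the threshold without control 1 (adjusted p = 0.062) and with no filter on low values. The list passed limma's camera test of a set against all other genes with a preset correlation of 0.01 (adjusted p = 3.90e-23), and had adjusted p = 0.33 with an estimated correlation.

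**Figure D2:**
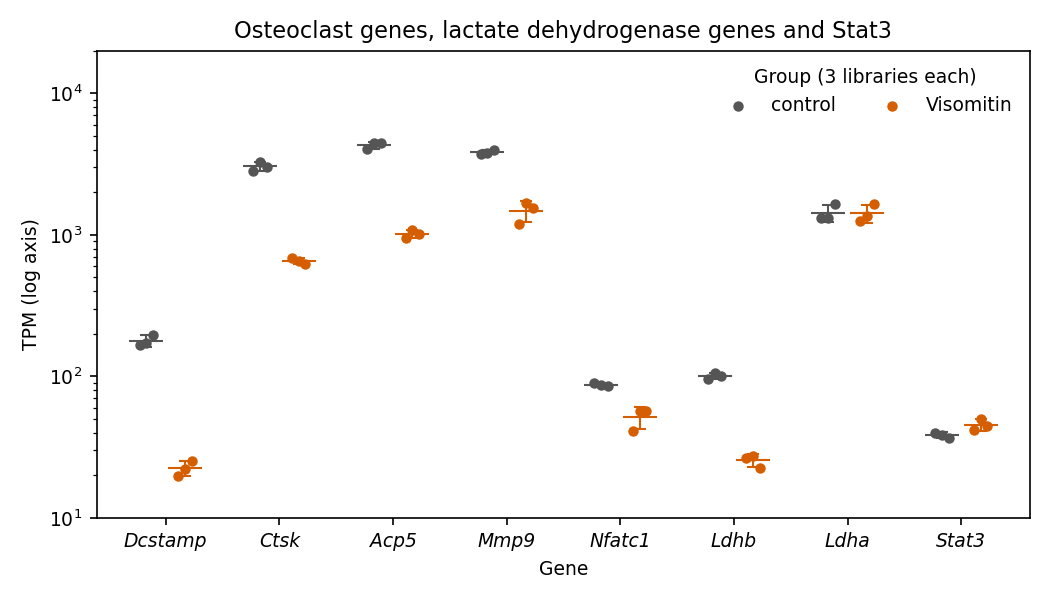
TPM (log axis) of 5 osteoclast genes, both lactate dehydrogenase genes and Stat3 in the 3 control (grey) and 3 Visomitin (orange) libraries; points are libraries, horizontal lines the means and bars 1 SD. Control and Visomitin libraries do not overlap for Dcstamp, Ctsk, Acp5, Mmp9, Nfatc1, Ldhb or Stat3 and overlap for Ldha, and Stat3 did not pass the test across all genes (adjusted p = 0.19).

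Subunits of the V-ATPase, the proton pump that acidifies lysosomes and the resorption space, were lower: 11 of 16 tested members fell, 0 rose and 5 did not pass (median -0.43; 14 fell adjusted over the list alone). Atp6v1b2 fell from 893 ± 53.1 to 418 ± 39.3 TPM (-1.10, SE 0.09, adjusted p = 0.00036), Atp6v1e1 from 509 ± 30.2 to 284 ± 18.5 TPM (-0.84, adjusted p = 0.00086) and Atp6v1h from 130.5 ± 10.99 to 75.8 ± 3.99 TPM (-0.77, adjusted p = 0.0025). The set passed camera (adjusted p = 3.08e-10) but not with an estimated correlation (adjusted p = 0.33). The count was 7 without control 1, 8 without Visomitin 3, and 6 without control 2, control 3 or Visomitin 2. Lysosomal hydrolases and membrane proteins went both ways. Of 30 tested, 1 rose and 2 fell (3 and 4 adjusted over the list alone), and the median was -0.02 (0.02 after median-ratio scaling) while camera pointed upward (adjusted p = 0.71). Without Visomitin 1, 5 rose and 4 fell, with a median of 0.04, and without each other library 0 rose and 0 fell. Gusb (-0.33), for a glycan-degrading enzyme, fell, and Ctsh (0.29), a cathepsin, rose. Both calls were lost when control 1, control 2, control 3, Visomitin 2 or Visomitin 3 was left out (adjusted p up to 0.14 for Gusb and 0.16 for Ctsh). With a library left out, the log2 fold change stayed at -0.37 to -0.27 for Gusb and at 0.28 to 0.31 for Ctsh. Gusb also missed the threshold under quantile normalization (0.055).

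Ldhb fell from 101 ± 5.28 to 25.5 ± 2.55 TPM (SD, n = 3; -1.94, SE 0.10, adjusted p = 3.03e-05), lower in 3 of 3 Visomitin libraries than in any control. Whether Ldhb fell within cells or through a smaller share of osteoclasts cannot be told apart in bulk RNA. Ldha, the A subunit gene and the more abundant of the pair, was at 1429 ± 187 and 1425 ± 207 TPM (-0.01, SE 0.13, adjusted p = 0.98). The difference was smaller than the spread between libraries and changed sign after median-ratio scaling (0.04). For Ldhb and for Stat3 the exact two-sided permutation test of the group labels gave p = 0.1, the smallest that 3 against 3 allows, and for Ldha it gave p = 1. Of 27 tested genes of glycolysis and lactate metabolism, 1 rose and 2 fell (3 and 2 adjusted over the list alone), with a median of 0.12. The median was 0.02 without Visomitin 3, 0.18 without control 3 and 0.20 without Visomitin 1, and the count that rose was 3 without Visomitin 1 and 0 without control 1, control 2, Visomitin 2 or Visomitin 3. Camera did not call the list (adjusted p = 0.099) but did without control 3 (0.0091) or Visomitin 1 (0.034). Besides Ldhb, the monocarboxylate transporter gene Slc16a7 fell from 30.9 ± 0.63 to 14.1 ± 3.73 TPM (-1.11, SE 0.18, adjusted p = 0.010). Aldoc, an aldolase, rose from 17.9 ± 0.19 to 25.4 ± 2.35 TPM (0.48, SE 0.10, adjusted p = 0.031). The call was lost without control 1, control 2, control 3, Visomitin 2 or Visomitin 3 (adjusted p up to 0.11). Pgk1, at 1220 ± 44.7 and 1546 ± 139 TPM, did not pass (0.34, adjusted p = 0.051; 0.036 without Visomitin 1 and 0.030 after median-ratio scaling).

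Stat3 itself had a log2 fold change of 0.23 (SE 0.10), higher in 3 of 3 Visomitin libraries than in any control, and passed only with array weights, which give libraries unequal weight (0.33, adjusted p = 0.018; range over all alternatives 0.018 to 0.49). Of 27 tested STAT3 pathway and target genes, 1 rose and 1 fell (5 and 2 adjusted over the list alone). The settings changed this count, with 6 rising and 1 falling after median-ratio scaling, 5 and 1 after quantile normalization, 8 and 2 with array weights, 7 and 2 after the length and GC correction, 2 and 3 with the library number as a block, and 0 and 0 with no filter on low values. Of these genes 3 rose without Visomitin 1, and 0 rose without control 1, control 2, control 3, Visomitin 2 or Visomitin 3. The count that fell was 2 without control 2 or Visomitin 3 and 0 without control 1 or Visomitin 2. The STAT3 target Pim1 rose from 12.7 ± 1.17 to 18.3 ± 1.18 TPM (0.50, SE 0.11, adjusted p = 0.035), and the cytokine gene Lif fell from 4.74 ± 1.17 to 1.75 ± 0.21 TPM (-1.04, SE 0.18, adjusted p = 0.014). Il10ra (0.45, adjusted p = 0.051) and the cyclin gene Ccnd1 (-1.31, adjusted p = 0.051) did not pass. The median of the list was 0.12 (0.19 without Visomitin 1 and 0.08 without Visomitin 3) and its mean 0.03. Camera called it higher (adjusted p = 0.022, and adjusted p = 0.71 with an estimated correlation). That call was lost without control 2 (0.097) or Visomitin 3 (0.065) or with the library number as a block (0.051). The list mixes STAT3 targets with receptors, kinases and inhibitors of the pathway, so its direction does not give that of STAT3 activity. Pim1 lost its call without control 1, control 2, control 3, Visomitin 2 or Visomitin 3 (adjusted p up to 0.11), and Lif without control 1 or Visomitin 2 (up to 0.056). Il10ra gained one without Visomitin 1 (0.039) or under the scalings (0.024 and 0.030), and Ccnd1 without control 2 (0.048) or Visomitin 3 (0.015).

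Mitochondrial respiration genes encoded in the nucleus were lower with Visomitin. Of 24 tested genes of the tricarboxylic acid cycle, 13 fell, 0 rose and 11 did not pass (median -0.39; 17 fell adjusted over the list alone), and all 24 had a value below 0. Idh3a, a subunit of isocitrate dehydrogenase, fell from 65.9 ± 1.92 to 34.8 ± 3.53 TPM (-0.90, SE 0.10, adjusted p = 0.0015). The malate dehydrogenase genes Mdh2, for the mitochondrial enzyme, and Mdh1, for the cytosolic one, fell from 562 ± 16.8 to 293 ± 40.9 TPM (-0.95, SE 0.11, adjusted p = 0.0020) and from 241 ± 14.98 to 161 ± 5.06 TPM (-0.58, SE 0.08, adjusted p = 0.0045). The list also holds the cytosolic Acly, and it shares Sdha, Sdhb, Sdhc and Sdhd with the oxidative phosphorylation list. Of 75 tested nuclear-encoded oxidative phosphorylation genes, 18 fell, 0 rose and 57 did not pass (median -0.26; 38 fell adjusted over the list alone). Cytochrome c (Cycs) fell from 37.3 ± 1.23 to 21.3 ± 1.97 TPM (-0.78, adjusted p = 0.0037) and Cyc1 of complex III from 176 ± 4.18 to 116 ± 10.04 TPM (-0.60, adjusted p = 0.0065). The ATP synthase genes Atp5g1 (-0.60, adjusted p = 0.0053) and Atp5g3 (-0.48, adjusted p = 0.0092) also fell. Camera called both lists lower (adjusted p = 2.90e-11 and 1.21e-12). Both had adjusted p = 0.39 with an estimated correlation. With 1 library left out, the count of tricarboxylic acid cycle genes was 5 without control 1, 6 without control 2 or Visomitin 2 and 7 without control 3. The count of oxidative phosphorylation genes was 6 without control 1 or 2, 7 without control 3 or Visomitin 2, 12 without Visomitin 3 and 37 without Visomitin 1; it was 55 with array weights, 11 with no filter on low values and 9 without the trend. The count of tricarboxylic acid cycle genes was 18 with array weights, and 8 with no filter or without the trend.

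Of the 13 mitochondrially encoded respiratory genes 0 passed limma, 0 adjusted over the list alone, and 3 had an unadjusted p under 0.05. Their median was 0.08 and their mean -0.01, with camera pointing upward (adjusted p = 0.77). Of these genes, 7 had a value above 0 and 6 below. The mean includes large values of opposite sign, 1.30 for mt-Atp6 and -2.12 for mt-Co3 (SE 1.79, adjusted p = 0.51). In Visomitin 2, mt-Co3 was listed at 0.30 TPM, against 458 and 103 TPM in Visomitin 1 and 3. The median was 0.14 without control 1, 0.05 without control 2, -0.03 without control 3, -0.13 without Visomitin 1, 0.20 without Visomitin 2 (where 1 gene rose) and 0.16 without Visomitin 3. The lowest p-values belonged to mt-Nd5 (-0.28, adjusted p = 0.12), mt-Nd6 (-0.38, adjusted p = 0.13) and mt-Atp6 (1.30, adjusted p = 0.16; 0.62 on the log2 scale without control 2). Without Visomitin 1, mt-Nd5 (-0.38, adjusted p = 0.023) and mt-Nd6 (-0.54, adjusted p = 0.0032) passed. These genes are uncertain, because nuclear genes such as Gm28437, listed at 3013 to 5455 TPM, are near-identical to them, and how shared reads were assigned is not given in the sources used here. Among 21 tested genes of mitochondrial biogenesis and turnover, 2 rose and 2 fell (2 and 3 adjusted over the list alone; median -0.12, camera adjusted p = 0.44). The median was -0.02 without control 1 and -0.21 without control 3. The count that rose was 1 without Visomitin 3 and 0 without each other library, and the count that fell was 1 without each library except Visomitin 1. Ppargc1b, a coactivator of mitochondrial biogenesis, fell from 16.2 ± 1.35 to 7.44 ± 1.52 TPM (-1.04, SE 0.15, adjusted p = 0.0059), as did the fusion gene Mfn2 (-0.41, adjusted p = 0.044). The mitophagy genes Bnip3 (0.52, adjusted p = 0.045) and Pink1 (0.50, adjusted p = 0.049; named after its values were seen) rose. Bnip3 lost its call whichever single library was left out (adjusted p up to 0.15), Mfn2 without each except Visomitin 1 (up to 0.13) and Pink1 without each except Visomitin 3 (up to 0.16).

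Genes of the ATF4 response to amino acid and mitochondrial stress were higher: 9 of 22 tested members rose, 0 fell and 13 did not pass (median 0.50; 10 rose adjusted over the list alone). Trib3, a pseudokinase, rose from 2.34 ± 0.36 to 20.4 ± 3.89 TPM (SD, n = 3; 2.67, SE 0.17, adjusted p = 7.86e-05). Ddit3, which encodes CHOP, rose from 15.6 ± 2.70 to 42.8 ± 4.15 TPM (1.41, SE 0.14, adjusted p = 0.00080), and the transcription factor gene Atf5 from 65.7 ± 9.67 to 131 ± 13.5 TPM (0.99, SE 0.12, adjusted p = 0.0034). Camera called the list higher (adjusted p = 1.40e-09, and adjusted p = 0.39 with an estimated correlation). Chaperones of the endoplasmic reticulum had a median below 0: of 15 tested, 1 rose and 2 fell (1 and 7 adjusted over the list alone; median -0.25, camera adjusted p = 0.0086, and adjusted p = 0.62 with an estimated correlation). Calr, for calreticulin, fell from 1168 ± 52.1 to 770.0 ± 84.6 TPM (-0.61, SE 0.10, adjusted p = 0.0092) and Hspa5, for BiP, from 301 ± 16.4 to 228 ± 17.4 TPM (-0.40, adjusted p = 0.030). Herpud1, which acts in the degradation of misfolded proteins, rose (0.71, adjusted p = 0.019). Hspa5 lost its call without control 1, control 2, control 3 or Visomitin 2 (adjusted p up to 0.11), and Herpud1 without control 1 or Visomitin 2 (up to 0.071). The count of chaperone genes that fell was 1 without each control library or Visomitin 2 and 4 without Visomitin 1.

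Antioxidant and NRF2 target genes, a group of interest for an antioxidant compound, included 6 that fell and 0 that rose among 33 tested (8 fell adjusted over the list alone; median -0.18). Mitochondrial thioredoxin (Txn2) fell from 207 ± 13.96 to 134 ± 13.1 TPM (-0.62, SE 0.10, adjusted p = 0.0090). Malic enzyme (Me1) fell from 21.7 ± 1.17 to 13.0 ± 1.64 TPM (-0.70, adjusted p = 0.012) and sulfiredoxin (Srxn1) from 190.0 ± 11.7 to 130 ± 13.6 TPM (-0.55, adjusted p = 0.016). Mitochondrial peroxiredoxin (Prdx3) fell from 98.0 ± 2.96 to 72.2 ± 3.75 TPM (-0.44, adjusted p = 0.018). Camera called the list lower (adjusted p = 0.037, and adjusted p = 0.71 with an estimated correlation), but not without Visomitin 3 (0.065), at a mean of at least 5 TPM (0.052), without the trend (0.055) or with array weights (0.076). The median was -0.11 without Visomitin 1, where 1 gene rose. The count that fell was 2 without control 1 or control 3 and 4 without control 2 or Visomitin 2. Srxn1 lost its call without control 1 or control 3 (up to 0.062) and Prdx3 without control 1, control 2, control 3 or Visomitin 2 (up to 0.082). Of 18 tested hypoxia and HIF1 target genes, 4 rose and 0 fell (5 and 2 adjusted over the list alone; median 0.14, camera adjusted p = 0.049, and adjusted p = 0.74 with an estimated correlation). Vegfa, a vascular growth factor gene, rose from 13.4 ± 1.91 to 27.4 ± 7.45 TPM (0.96, adjusted p = 0.022). Ndrg1 (0.60, adjusted p = 0.021), the prolyl hydroxylase gene Egln3 (1.01, adjusted p = 0.040) and Bnip3 also rose. Vegfa missed the threshold without control 1, control 2 or Visomitin 2 (up to 0.085), Ndrg1 without control 1 or Visomitin 2 (up to 0.074) and Egln3 without each library except control 3 (up to 0.12). The list call ended without control 1 (0.10), control 2 (0.22) or Visomitin 3 (0.12) and under either scaling (0.061 and 0.075), and with pseudocount 5, a mean of at least 5 TPM, no trend, array weights or the length and GC correction (up to 0.091). The median was 0.22 without control 3, 0.25 without Visomitin 1, where 1 gene fell, and 0.03 without Visomitin 3. The count that rose was 0 without control 1 or Visomitin 2, 1 without control 2 and 2 without Visomitin 3.

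**Figure D3:**
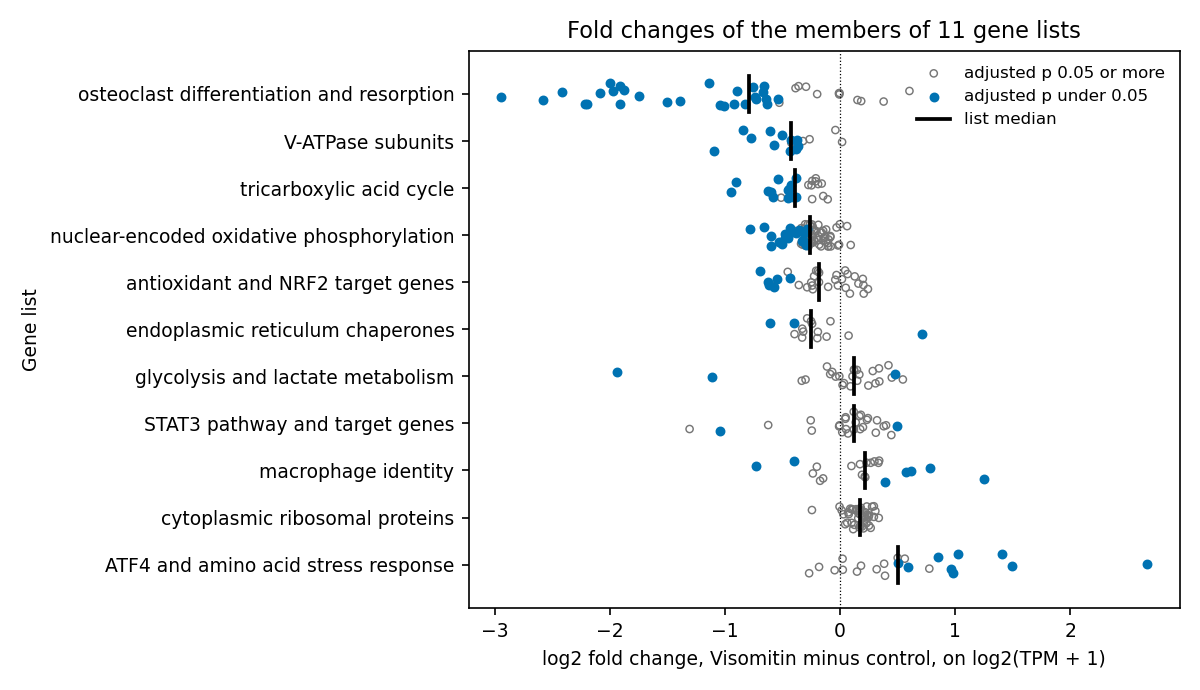
Log2 fold change (Visomitin minus control, on the log2(TPM + 1) scale, x axis) of each tested member of the gene lists named on the y axis; filled points passed an adjusted p of 0.05 over all genes, open points did not, and black bars are list medians. Medians run from -0.79 for osteoclast genes to 0.50 for ATF4 genes, and ribosomal protein genes lie close together around 0.17 with 0 past the test.

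Macrophage identity genes went both ways. Of 21 tested, 5 rose, 2 fell and 14 did not pass (8 and 2 adjusted over the list alone; median 0.22, camera adjusted p = 0.0029, and adjusted p = 0.62 with an estimated correlation). Cd86, a co-stimulatory receptor, rose from 2.65 ± 0.74 to 7.63 ± 1.29 TPM (1.25, SE 0.19, adjusted p = 0.0070). The mannose receptor gene Mrc1 rose from 67.6 ± 7.04 to 104 ± 8.41 TPM (0.61, adjusted p = 0.012) and the efferocytosis receptor Mertk from 17.2 ± 1.70 to 26.0 ± 2.03 TPM (0.57, adjusted p = 0.022). Cx3cr1 (0.78) and Fcgr3 (0.39) also rose, and Clec7a (-0.73) fell; these 3 were named after their values were seen. The folate receptor gene Folr2 fell from 293 ± 7.90 to 221 ± 5.48 TPM (-0.40, adjusted p = 0.014). Of these 7, only Cd86 kept its call in every alternative tried. Mrc1 lost it without Visomitin 2 (0.053), and Folr2, Mertk and Cx3cr1 without control 1, control 2, control 3 or Visomitin 2 (up to 0.074, 0.096 and 0.083). Fcgr3 lost it without each library except Visomitin 1 (up to 0.10) and Clec7a without each except control 3 (up to 0.14). The count that rose was 9 without Visomitin 1, 2 without each control library and 1 without Visomitin 2, and the count that fell was at most 1 whichever library was left out. Of 13 tested negative regulators of osteoclast formation, 1 rose and 1 fell (3 and 2 adjusted over the list alone), while 3 rose under either scaling, 2 without Visomitin 1 and 0 without Visomitin 2. Irf8, a transcription factor that restrains osteoclast formation, rose from 57.6 ± 6.61 to 88.8 ± 5.25 TPM (0.62, adjusted p = 0.012; 0.054 without Visomitin 2). Tnfaip3, an inhibitor of NF-kB signalling, fell from 34.1 ± 2.50 to 17.5 ± 2.75 TPM (-0.93, adjusted p = 0.0053), and Pias3 did not pass (0.31, adjusted p = 0.080; 0.036 and 0.034 under the scalings). The median was -0.09 (-0.04 without control 3, -0.03 without Visomitin 2 and -0.18 without Visomitin 3) while camera pointed upward (adjusted p = 0.87).

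Inflammatory genes went both ways: of 22 tested, 2 rose and 5 fell (2 and 6 adjusted over the list alone; median -0.14, camera adjusted p = 0.31). The median was -0.09 without control 2, -0.08 without control 3 and -0.05 without Visomitin 1. The count that fell was 3 without each library except Visomitin 3, and the count that rose was 1 without control 1, control 2 or Visomitin 2. The chemokine gene Ccl8 fell 4.85-fold, from 20.02 ± 3.26 to 3.31 ± 0.35 TPM (-2.28, SE 0.14, adjusted p = 8.00e-05). Il1rn, for the interleukin 1 receptor antagonist, fell from 135 ± 4.599 to 71.9 ± 7.85 TPM (-0.90, adjusted p = 0.0015) and Ccl9 from 445 ± 22.0 to 316 ± 9.14 TPM (-0.49, adjusted p = 0.0075). Named after their values were seen, Tnf (-1.11) and Ccl12 (-0.89) fell and Il18 (0.82) and Nlrp3 (0.53) rose. Of these 4, Il18 alone kept its call without each library. Tnf and Ccl12 lost theirs without each library except Visomitin 3 (up to 0.14 for both), and Nlrp3 without control 1, control 2, Visomitin 2 or Visomitin 3 (up to 0.11). Among 7 tested genes of MHC class II presentation, 2 rose and 2 fell (3 and 3 adjusted over the list alone; median -0.28, or -0.16 without Visomitin 3; camera adjusted p = 0.77). The count that rose was 1 without control 1 and 0 without each other library, and the count that fell was 1 without each library except Visomitin 1. Cd74, the invariant chain, fell from 519 ± 70.2 to 246 ± 26.3 TPM (-1.07, SE 0.12, adjusted p = 0.0017) and the class II chain gene H2-Aa from 60.0 ± 12.2 to 34.2 ± 5.96 TPM (-0.79, adjusted p = 0.028). The peptide-loading genes H2-DMa (0.77, adjusted p = 0.036) and H2-DMb1 (0.43, adjusted p = 0.047; named after its values were seen) rose. H2-Aa lost its call without each library except Visomitin 1 (up to 0.093) and under both scalings (0.055), H2-DMa without each except control 1 (up to 0.10) and H2-DMb1 whichever library was left out (up to 0.14). Of 7 tested genes of alternative activation, the lectin gene Clec10a rose from 11.5 ± 1.98 to 24.2 ± 3.85 TPM (1.01, adjusted p = 0.0098) and Egr2 fell (-0.84, adjusted p = 0.012; 0.056 without control 1), 1 and 1 adjusted over the list alone. Klf4 did not pass (0.35, adjusted p = 0.21). The median was -0.004 (0.04 after median-ratio scaling and 0.07 after quantile normalization) and the mean 0.04, with camera pointing upward (adjusted p = 0.61). Without Visomitin 3 the median was -0.08, and without each other library it was above 0, up to 0.29 without control 3. Of 29 tested interferon-stimulated genes 0 passed limma, 0 adjusted over the list alone, and 5 had an unadjusted p under 0.05. Rtp4 (-0.62, adjusted p = 0.093), Oasl1 (-0.60, adjusted p = 0.10) and Oas1a (-0.37, adjusted p = 0.11) came closest, and the list had a median of -0.08 (camera adjusted p = 0.77). That median was -0.18 without control 1, 0.05 without control 2, -0.13 without control 3, -0.03 without Visomitin 1 and -0.14 without Visomitin 2.

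The 10 genes with the largest rise also included Cox6a2, an isoform of a cytochrome c oxidase subunit typical of muscle, from 0.52 ± 0.15 to 5.67 ± 2.23 TPM (2.07, SE 0.27, adjusted p = 0.0036), and Gadd45a, a growth arrest gene, from 8.74 ± 1.39 to 24.96 ± 3.48 TPM (1.42, SE 0.15, adjusted p = 0.0011). Chac1, whose product degrades glutathione, rose from 1.34 ± 0.57 to 5.51 ± 1.10 TPM (2.82-fold, adjusted p = 0.0073). Entpd1, the ectonucleotidase CD39, rose from 16.4 ± 1.51 to 51.8 ± 24.2 TPM (1.47, adjusted p = 0.037). The call was lost without each library except Visomitin 2 (up to 0.11) and with array weights (0.79, adjusted p = 0.092). Gpr141, an orphan receptor gene, rose from 4.31 ± 1.48 to 11.6 ± 2.11 TPM (1.27, adjusted p = 0.017), and lost its call without Visomitin 1 (0.052) or Visomitin 2 (0.059). Cd300ld5 (2.35, adjusted p = 0.034) and Hist1h2af (1.25, adjusted p = 0.035) belong to families of near-identical genes, so their values are uncertain. Cd300ld5 lost its call without each library except control 2 (up to 0.11). It also lost it with pseudocount 0.1, with no filter on low values and without the trend (adjusted p up to 0.14 over all alternatives). Its log2 fold change was 3.80 with pseudocount 0.1 and 1.18 with pseudocount 5. Hist1h2af lost its call whichever single library was left out (up to 0.081).

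The genes with the largest fall, beyond those of the osteoclast list, were Kbtbd11, from 29.8 ± 5.41 to 2.81 ± 0.46 TPM (-3.00, SE 0.16, adjusted p = 4.05e-05), and Akr1c18, a hydroxysteroid dehydrogenase, from 54.7 ± 3.50 to 6.14 ± 1.30 TPM (-2.98, SE 0.15, adjusted p = 2.61e-05). Mt3, a metallothionein, fell from 295 ± 19.7 to 40.8 ± 7.04 TPM (-2.84, SE 0.13, adjusted p = 1.71e-05), and Steap4, a metalloreductase, from 16.6 ± 0.90 to 1.497 ± 0.14 TPM (-2.82, SE 0.12, adjusted p = 1.71e-05). The tetraspanin gene Tspan7 fell 6.08-fold, the myosin gene Myo1d 4.98-fold and Cd200, an immune inhibitory ligand, 4.90-fold. All 7 calls held without each library and in every alternative tried.

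Of 48 tested ribosomal protein genes, 46 had a value above 0, and the median was 0.17. Limma passed 0 of them, and 0 adjusted over the list alone, with 18 at an unadjusted p under 0.05. The count that rose was 3 without Visomitin 1, 1 without Visomitin 3, 2 under quantile normalization (Rps7 and Rplp2), 7 after the length and GC correction and 13 with array weights. Rps7 (0.34, adjusted p = 0.053; 0.044 without Visomitin 1 and 0.048 without Visomitin 3), Rps20 (0.29, adjusted p = 0.091) and Rplp2 (0.28, adjusted p = 0.092) had the lowest p-values. Camera called the list higher (adjusted p = 3.30e-10, and adjusted p = 0.51 with an estimated correlation). Of 40 tested cell cycle genes 0 passed limma, 0 adjusted over the list alone, and 3 had an unadjusted p under 0.05. The median was -0.05 (0.02 without Visomitin 1, -0.14 without Visomitin 3 and -0.02 to -0.03 without control 1, control 3 or Visomitin 2) while camera pointed upward (adjusted p = 0.77). The 3 genes were Ccnb2 (0.40, adjusted p = 0.070), Bub1b (0.27, adjusted p = 0.099) and Ccne1 (-0.47, adjusted p = 0.13), of which Ccnb2 passed without control 2 (adjusted p = 0.045) or under quantile normalization (0.049) and Bub1b without Visomitin 1 (0.034) or under either scaling (0.025). Among 16 tested p53 target genes, Mdm2 (-0.42, adjusted p = 0.034) and Aen (-0.80, adjusted p = 0.046) fell and Sesn2 (0.51, adjusted p = 0.043), also an ATF4 target, rose, and 2 rose and 2 fell adjusted over the list alone. The median was -0.01 (0.03 and 0.05 under the scalings) while camera pointed upward (adjusted p = 0.77). The median ran from -0.09 without control 3 and -0.08 without Visomitin 2 to 0.06 without control 1, with 0.02 without Visomitin 1 and 0.05 without Visomitin 3. With control 1, control 2, control 3 or Visomitin 2 left out, 0 rose and 0 fell; 2 rose and 1 fell without Visomitin 1, and 0 rose without Visomitin 3. Mdm2 lost its call without control 1, control 2, control 3 or Visomitin 2 (up to 0.12), Aen without each library except Visomitin 3 (up to 0.14) and Sesn2 without each except Visomitin 1 (up to 0.15).

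Cholesterol synthesis and uptake genes had a median of -0.28, and 1 of 23 tested fell, Insig1 (-0.45, adjusted p = 0.046; lost whichever single library was left out, up to 0.15); adjusted over the list alone, limma passed 0, and 12 had an unadjusted p under 0.05. Idi1 did not pass (-0.45, adjusted p = 0.077). Camera called the list lower (adjusted p = 0.013, and adjusted p = 0.62 with an estimated correlation). Of 33 tested genes of fatty acid synthesis and oxidation, 2 fell, Etfdh (-0.46, adjusted p = 0.033) and the sterol receptor gene Nr1h3 (-0.39, adjusted p = 0.047), and 4 adjusted over the list alone. The count that fell was 3 without Visomitin 1, 1 without control 3 and 0 without control 1, Visomitin 2 or Visomitin 3. Cd36 did not pass (-0.52, adjusted p = 0.053; 0.048 without control 2). The list had a median of -0.13, and camera called it lower (adjusted p = 0.041, and adjusted p = 0.51 with an estimated correlation). That call was lost without control 1 (0.052), Visomitin 2 (0.052) or Visomitin 3 (0.12) and under both scalings (0.066 and 0.067), and at a mean of at least 5 TPM, without the trend, with array weights, with protein-coding genes only or after the length and GC correction (up to 0.072). Etfdh lost its call without each library except control 3 (up to 0.12) and Nr1h3 without each except Visomitin 1 (up to 0.14) and under both scalings (0.065 and 0.074). Of 15 tested heat shock and immediate early genes, Hsp90aa1, for a cytosolic chaperone, fell from 77.3 ± 5.03 to 42.1 ± 7.53 TPM (-0.88, adjusted p = 0.0088), 1 adjusted over the list alone (median -0.20, or -0.12 without Visomitin 1; camera adjusted p = 0.16). Hsph1 (-0.40, adjusted p = 0.079) and Fos (-0.53, adjusted p = 0.099; 0.046 without Visomitin 3) did not pass.

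Markers of other cell types were mostly near 0 TPM. At least 5 TPM in some library was reached by 0 of 9 erythroid, 0 of 10 mast cell and basophil, 2 of 10 B cell, 2 of 11 T and NK cell and 1 of 7 megakaryocyte markers. It was reached by 3 of 15 neutrophil, 1 of 9 dendritic cell and 10 of 17 stromal and osteoblast markers. Stromal collagen genes varied between control libraries: Col1a1 was at 95.8, 48.9 and 139 TPM in control 1 to 3 and at 47.9 ± 21.1 TPM with Visomitin (-0.94, adjusted p = 0.20). Col6a1 (-1.36, adjusted p = 0.10; -1.85 and 0.016 without control 2) and Dcn (-0.49, adjusted p = 0.15) were also below 0. Of 11 tested stromal markers 10 had values below 0, 0 passed limma, 0 adjusted over the list alone, and 3 had an unadjusted p under 0.05. The list missed camera (adjusted p = 0.070, and 0.77 with an estimated correlation) but passed it without control 2 (0.00020), the control library with the lowest Col1a1. It also passed with quantile normalization (0.0497), no filter on low values (0.035), a block for the library number (0.021) or the length and GC correction (0.047), and adjusted p ranged up to 0.44 without control 3. The median was -0.65, and -1.04 without control 2, where 2 genes fell, -0.35 without control 3 and -0.43 without Visomitin 1. Itgax, for the CD11c integrin that macrophages also carry, fell from 26.3 ± 3.05 to 8.60 ± 1.59 TPM (-1.52, SE 0.15, adjusted p = 0.00094). The other tested dendritic markers, Batf3 (0.56, adjusted p = 0.24) and Zbtb46 (-0.03, adjusted p = 0.94; 0.05 under quantile normalization), did not pass. Ighm rose from 1.74 ± 0.50 to 4.21 ± 1.33 TPM (0.91, adjusted p = 0.0497; lost without each library except Visomitin 1, up to 0.15, and with pseudocount 0.1 or 5, with no filter on low values or without the trend). Cd22 was at -0.52 (adjusted p = 0.21) and Cd79a and Pax5 were listed at 0 in all 6 libraries. The tested neutrophil markers Csf3r (0.45, adjusted p = 0.10), Mmp8 (-0.36, adjusted p = 0.13) and S100a8 (-0.42, adjusted p = 0.32) did not pass, though 1 rose and 1 fell adjusted over the list alone. Nor did the T cell markers Il7r (-0.22, adjusted p = 0.25) and Cd4 (0.24, adjusted p = 0.58) or the megakaryocyte markers Pf4 (0.21, adjusted p = 0.47) and Ppbp (0.09, adjusted p = 0.79) pass.

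Counts in other lists also depended on the settings. Array weights gave 12 macrophage genes that rose, 13 ATF4 genes that rose, 13 NRF2 target genes that fell and 3 that rose, 9 lysosomal genes that rose and 5 that fell, and 7 glycolysis genes that rose and 3 that fell. They gave 7 chaperone genes that fell, 9 fatty acid genes that fell and 3 that rose, 6 cholesterol genes that fell and 1 that rose, and 6 hypoxia genes that rose and 2 that fell. Under them 4 negative regulators rose and 2 fell, 4 mitochondrially encoded genes fell and 1 rose, and 3 interferon-stimulated genes fell and 1 rose. Of the genes named above as not past the test, Stat3, Pias3, Pgk1, Il10ra, Ccnd1, mt-Nd5, mt-Nd6, mt-Atp6, Ccnb2, Bub1b, Ccne1, Rtp4, Oasl1, Oas1a, Klf4, Idi1, Cd36, Hsph1, Fos, Rps7, Rps20, Rplp2 and Csf3r passed with array weights. With no filter on low values, 24 osteoclast and 7 V-ATPase genes fell, 6 ATF4 genes rose, 2 macrophage genes rose, 3 NRF2 target genes fell, and 0 genes of the chaperone, hypoxia, p53, cholesterol, fatty acid and alternative activation lists passed. Without the trend, 7 V-ATPase genes fell, 7 ATF4 genes and 2 hypoxia genes rose, and 0 genes of the lysosomal, p53 and fatty acid lists passed.

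Osteoclast, V-ATPase, respiration and ATF4 genes made up the set calls with the smallest p-values apart from the ribosomal list. Of 26 gene lists with at least 5 tested members, 13 passed camera, 5 higher and 8 lower. With an estimated correlation 0 of the 13 remained, the lowest adjusted p being 0.33. That form of camera rests on 4 residual degrees of freedom and missed even the osteoclast list, where 28 of 40 genes fell. Its misses therefore cannot decide whether a list changed. The fry test, which asks whether a list's genes move one way on balance, passed 6. These were the osteoclast, V-ATPase, tricarboxylic acid cycle, nuclear-encoded oxidative phosphorylation, ATF4 and fatty acid lists (fry adjusted p = 0.0019 to 0.038). The other lists called by camera missed fry. Adjusted p was 0.062 for cholesterol, 0.063 for chaperone and 0.083 for NRF2 target and ribosomal genes. It was 0.13 for macrophage identity, 0.31 for STAT3 and 0.43 for hypoxia genes. Other splits of the 6 libraries into 3 and 3 passed up to 11 lists in camera with the preset correlation. Those splits mix both groups on each side and carry part of any Visomitin difference, so these calls need not be due to chance.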

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

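Tests on protein-coding genes only and with a length and GC correction were chosen after seeing the data. Ldhb, Acp5, Ctsk, Dcstamp, Mmp9, Ckb, Atp6v1b2, Idh3a, Mdh2, Trib3, Ddit3 and Atf5 passed the test in every alternative tried. Of 116 named gene results, 79 passed the test (limma), 41 of them in every alternative and 45 with each library left out. With no filter on low values 33 of the 79 calls were lost, and without the trend 18. Over all alternatives the named genes gave 2065 comparisons, of which 1770 kept direction and side of the threshold, 200 became weaker, 83 became stronger and 12 reversed. The lists gave 465, of which 402 stayed, 27 became weaker, 7 became stronger and 29 reversed, and 9 lists passed camera in every alternative at the preset correlation. With an estimated correlation 0 lists passed, the lowest adjusted p being 0.33. Ldhb kept a log2 fold change of -1.99 to -1.86 with each library left out.

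The number of genes past the threshold was 381 with no filter on low values (73 higher and 308 lower), where more genes of low level were tested. It was 2835 with array weights (1263 and 1572) and 1465 with the length and GC correction (709 higher). The higher genes numbered 481 after median-ratio scaling and 559 after quantile normalization. With 1 library left out, the total ran from 299 to 983, the higher genes from 54 to 411 and the lower genes from 232 to 577. The 983 came without Visomitin 1, the library that stands apart on the second component, and the 299 without control 1. These fits have fewer residual degrees of freedom than the main fit, and how much of the fall in counts is lost power was not tested. At least a 2-fold change was seen for 80 genes with pseudocount 5, which shrinks the change of low genes, and for 127 at a mean of at least 5 TPM, where fewer genes were tested. With the library number as a block the total was 1107. The residual correlations within a number (0.05, 0.02 and 0.17) were small but positive, so pairing by number is neither shown nor excluded. Stat3 passed with array weights alone (0.33, adjusted p = 0.018, range over all alternatives 0.018 to 0.49). Where no reason is given, the cause was not tested.

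Ldha had 0.036 after median-ratio scaling, 0.025 with array weights, 0.055 with the length and GC correction and -0.12 to 0.099 with 1 library left out. Cd4 had -0.048 with array weights, and Zbtb46 0.049 after quantile normalization, 0.062 with array weights, 0.038 with the length and GC correction and -0.080 to 0.077 with 1 library left out. With array weights, the list medians were -0.038 for mitochondrially encoded genes, 0.034 for lysosomal genes and 0.12 for alternative activation. Median-ratio scaling gave 0.023 for lysosomal genes, 0.034 for p53 targets and 0.037 for alternative activation, and quantile normalization gave 0.045 for p53 targets and 0.074 for alternative activation. The length and GC correction gave 0.032 for lysosomal genes, 0.031 for cell cycle genes, 0.064 for p53 targets and 0.071 for alternative activation. Alternative activation had 0.020 with pseudocount 0.1, and MHC class II genes 0.21 with no filter and 0.080 with protein-coding genes only. With 1 library left out the list medians ran from -0.13 to 0.20 for mitochondrially encoded, -0.065 to 0.043 for lysosomal, -0.14 to 0.024 for cell cycle, -0.092 to 0.060 for p53 target, -0.18 to 0.053 for interferon-stimulated and -0.075 to 0.29 for alternative activation genes. Mitochondrially encoded genes have no value where they were left out, and alternative activation had too few genes at a mean of 5 TPM. The median of all tested genes was -0.034 in the main fit and 0.003 after median-ratio scaling. It was 0.023 after quantile normalization and 0.026 after the length and GC correction. A shift of all genes can alone turn the sign of values this near 0 under these 3 settings. The cause of the other reversals was not tested. Depth is unknown, so what it limits cannot be given.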

Other observations

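The tests of mitochondrial RNA content, of the osteoclast share, of the chaperones of the endoplasmic reticulum and of the ATF4 genes without each Visomitin library were chosen only after the result was seen, as was the length and GC correction, and so were the genes of the next 2 paragraphs.

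Tfrc, the transferrin receptor gene, fell from 48.7 ± 2.49 to 15.6 ± 1.44 TPM (limma log2 fold change -1.58, adjusted p = 8.14e-05, and -1.64 to -1.52 with each library left out), lower in 3 of 3 Visomitin libraries than in any control. Steap4, a metalloreductase gene, fell by 2.82, while Slc11a2 (-0.50, adjusted p = 0.079) and Steap3 (-0.43, adjusted p = 0.063; 0.039 without Visomitin 3) did not pass. Hfe, which encodes a partner of the transferrin receptor, rose (0.58, adjusted p = 0.018), a call lost without control 1, control 2 or Visomitin 2 (adjusted p up to 0.079). The ferritin genes Fth1 (0.09, adjusted p = 0.55) and Ftl1 (0.20, adjusted p = 0.16) did not pass. Among metallothioneins, Mt3 fell by 2.84, Mt1 did not pass (-0.02, adjusted p = 0.96), and Mt2 rose (0.48, adjusted p = 0.045), a call lost without control 1, control 2, control 3 or Visomitin 3 (adjusted p up to 0.14).

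Ckmt1, the mitochondrial creatine kinase gene, fell from 10.1 to 1.60 TPM (-2.09, adjusted p = 0.00031), and Bdh1, for a ketone body enzyme, from 30.0 to 8.19 TPM (-1.75, adjusted p = 0.00010). Pck2, the mitochondrial form of phosphoenolpyruvate carboxykinase, rose from 20.6 to 46.9 TPM (1.15, adjusted p = 0.00065). Spp1 (-1.13, adjusted p = 0.00083) and Mmp12 (-1.04, adjusted p = 0.00084), secreted products of osteoclasts and macrophages, fell, and Fcgr2b (0.93, adjusted p = 0.00079) and the heparanase gene Hpse (1.13, adjusted p = 0.00056) rose. All 7 limma calls held with each library left out. Gm12112 was listed at 0 in all Visomitin libraries and at 7.10, 11.66 and 8.20 TPM in control 1 to 3. The unnamed gene ENSMUSG00002076896 was listed at 0 in all control libraries and at 19.35, 44.53 and 19.77 TPM in Visomitin 1 to 3.

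Ribosomal protein genes had a median log2 fold change of 0.17 with Visomitin, though 0 of 48 passed limma. Their transcripts are short, with a median of 680.5 bases against 1290.5 for tested genes. After the length and GC correction the median fold change of the list was 0.24, which argues against such a trend as the whole cause. The median of all tested genes also moved, from -0.034 to 0.026, so much of the increase was shared by all genes. The lowest median without a Visomitin library was 0.12, without Visomitin 1, where the median of all tested genes was 0.013. The lowest under the scalings was 0.15, with quantile normalization, where that of all tested genes was 0.023. Neither a single Visomitin library nor the scaling therefore explains the shift alone. The shift may be an effect of Visomitin. Camera did not call the list with an estimated correlation (adjusted p = 0.51), but that form has little power here and cannot decide. Differences in RNA quality or handling between the groups stay open and untested.

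Tricarboxylic acid cycle and nuclear-encoded respiratory genes were lower with Visomitin, though 11 of 24 and 57 of 75 members did not pass limma. Neither list passed camera with an estimated correlation (adjusted p = 0.39 for both). Of 30 called genes in both lists 25 were still called lower under whichever scaling kept fewer, which argues against scaling as the whole cause. Those genes were picked by their calls, but the medians over all tested members also stayed below 0 under the scalings, at -0.35 and -0.32 for the tricarboxylic acid cycle and -0.22 and -0.20 for nuclear-encoded oxidative phosphorylation. A lower mitochondrial RNA content of the cells stays open, since the pooled log2 fold change of mitochondrially encoded genes and their near-identical copies was -0.14 (SE 0.21, exact permutation p = 0.4), against a median of -0.27 for the nuclear genes. That test ignores the library numbers. Within each number the pooled share was lower with Visomitin (5.13 against 5.29%, 3.96 against 4.46% and 3.42 against 3.96%), though pairing by number is not shown. A smaller share of osteoclasts, cells rich in mitochondria, also stays open. Falls of 8 genes chosen as restricted to osteoclasts (Ctsk, Acp5, Dcstamp, Ocstamp, Oscar, Calcr, Siglec15 and Atp6v0d2) ran from -1.75 to -2.94, a spread of 1.20, while Mmp9 (-1.39) and Nfatc1 (-0.76) of the same list fell less. The range depends on that choice. A loss of cells with 1 common factor may not cover all 8, yet a lower share and a weaker program in each cell cannot be told apart in bulk RNA. The same limit holds for the V-ATPase genes and for Ldhb, whose fall (-1.94) lies within that range.

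ATF4 target genes were higher with Visomitin, and a candidate explanation is an unfolded protein response of the endoplasmic reticulum. Its chaperone genes had a median of -0.25, with 13 of 15 at or below 0, which argues against a full response of that kind in the culture as a whole, although Herpud1 rose and the PERK branch alone was not tested apart. A shift in the mix of cells, left open above, could also move these genes in bulk RNA. A response in part of the cells is therefore not excluded. A single Visomitin library does not account for the pattern either, since the median of the whole list was 0.50, and without a Visomitin library the lowest was 0.39 (without Visomitin 3), with the list still past camera at the preset correlation, though it did not pass with an estimated correlation (adjusted p = 0.39). Amino acid shortage and a mitochondrial stress response to Visomitin stay open, and no measure of either was analysed here.

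Grouping of the libraries by chance was examined with all 10 splits of the 6 libraries into 3 and 3. The real split gave 835 genes, 199 of them at least 2-fold, and the highest of the other splits gave 3 and 3. For gene lists past camera the real split gave 13 and the highest other 11. In each of these 3 counts 1 of the 10 splits, the real one, gave as large a result, and 10 splits are too few for a share under 0.05. Each other split also holds libraries of both groups on each side. It carries part of any Visomitin difference and puts the rest into the spread within its sides. The other splits are therefore not a reference without an effect.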
